A study of Rattus norvegicus with 2 samples.

How the data were processed

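Small RNA was sequenced from the left ventricle of Wistar rats aged 16 weeks. One library came from the control group and 1 from the group that swam. The swimming group had 2 sessions of 90 minutes a day over 8 weeks, per the labels' protocols. Total RNA was isolated with a miRNeasy kit and made into libraries by Illumina's small RNA method, per the labels' protocols. How many animals gave RNA to each library is not given in the sources used here.

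The authors deposited 1 table of counts per library. The values are whole numbers that sum to a different total in each library, and they were taken as counts with no scaling. The values alone cannot show whether a part of the table was scaled, and the intervals below rest on this reading. Bowtie 0.12.2 and the genome builds rn5 and rn4 are named, per the submitters' processing notes, with no role or order. The adapter trimming, the rule for reads that match several hairpins, the miRNA annotation release and the low-count rule are not given in the sources used here. The rows carry hairpin names, so both arms of a hairpin share a row.

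Each table held 203 rows with the same names in the same order. One row, named Others, names no miRNA. It held 5.41% of all counts in the control library and 12.5% in the swim library, and it was left out of library totals and comparisons. The 9 rows marked with an asterisk repeated the counts of the unmarked row of the same name in both libraries and were left out as repeats. The name let-7e was listed in 2 unmarked rows, with counts of 1193 in control and 821 in swim in one row and the reverse in the other. Its rows were kept in the totals but given no ratio. This left 191 entries with a ratio. Of the 15 hairpins with several genomic copies listed, 11 (such as mir-19b-1 and mir-19b-2) had equal or nearly equal counts per copy, so for these the same reads appear to stand in each copy's row. The copies of mir-92a, mir-7a, mir-128 and mir-218a had different counts. A count of 1 stood in 8 entries of the control library and 16 of the swim library, with no entry between 1 and 5 in either, so 1 may be a filled-in value.

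The table is made of 2 ordered parts. The first 81 rows stand in falling order of the swim-to-control ratio, and the other 122 rows in falling order of the control count. Leaving aside let-7e and Others, the higher of the 2 counts was at least 838 in every row of the first part, and no count was above 795 in the second part. Results are therefore also given within each part.

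Counts were divided by the library's total over the unmarked miRNA rows and expressed as CPM (the usual depth-scaled count). The totals were 2460845 in control and 3219939 in swim. For each entry the ratio of swim to control was computed with an exact conditional binomial (Clopper-Pearson) 95% interval. These intervals cover counting error only, and reads amplified by PCR without molecular identifiers are not independent molecules. With 1 library per condition there is no spread between animals, so no test across conditions was made and no p-value is attached to any entry. An entry was called higher or lower by a fixed rule of size: a log2 ratio, with a pseudocount of 0.5 added to each count, of at least 1 in size (2-fold) and a 95% interval that excluded 1. The 173 entries with a summed count of at least 20 entered, which stand for 157 distinct miRNAs.

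Before the data were examined, 22 lists of miRNAs were fixed by family, genomic cluster, cell type or topic, and the rule for the entries named in the text. That rule takes the 10 most abundant entries, up to 10 entries with the highest and up to 10 with the lowest ratio among those with a summed count of at least 100, and from each list the 4 most abundant members or all members where at most 7 were measured. Entries that the report names beyond it are said to be so. A list name was matched to every copy of that hairpin. Where the plain name was not listed its "a" form was used, as for mir-126a and mir-409a. For the 15 lists with at least 3 entries the median log2 ratio was placed among the medians of 10000 random lists of the same size, each member being replaced by 1 of the 20 entries outside the list nearest to it in mean abundance. This percentile describes these libraries and is not a test between conditions. Several lists share members.

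Alternatives fixed in advance were median-of-ratios size factors, the TMM factors of edgeR 4.0.16 (used only for these factors), a total without the most abundant entry, no rescaling, pseudocounts of 1 and 5, other filters on the summed count, size rules of 1.5 and 3-fold, and summed hairpin copies. The ratio rule and the random lists were tested on data simulated from these libraries' means and totals. For swim against control, with 40 entries changed 3-fold in each of 20 simulations of 169 to 177 entries, 96.9% of the changed entries were called in the right direction, 0.291% of the unchanged entries were called, and 96.4% of the intervals held the true ratio. Of 200 lists drawn at random, 11 lay outside the central 95%. Simulated counts were Poisson draws made for each row alone, with no spread between animals, PCR repeats or reads shared by copies. The ratios used the totals from which the counts were drawn, and as many entries were raised as lowered, so an error of scaling could not show. These rates therefore hold for counting error only. All 173 entries matched a name in a RefSeq gene table of a different rat assembly (GRCr8), which was used only to see which hairpins neighbour each other, so no coordinates are given. Computing was done in Python 3.11.15 with scipy 1.17.1 and in R 4.3.3.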

Results

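The study profiled small RNAs of the rat heart to compare animals whose hearts had grown through swimming training, a model of physiological hypertrophy, with controls. Each condition was represented by 1 left ventricular library. The control library held 2460845 counts over the miRNA entries and the swim library 3219939, a ratio of 1.31. Because neither condition was replicated, every difference below is a difference between these 2 libraries, and its interval covers counting error only. The terms higher and lower as calls refer to the 2-fold size rule.

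Both libraries were dominated by the same few miRNAs. The entry mir-143, enriched in vascular smooth muscle, was the most abundant in each, with 19.8% of the counts in control (95% exact binomial interval 19.7 to 19.8%) and 18.5% in swim (18.5 to 18.6%). The entry mir-30a took 11.3% in control and 16.6% in swim. For mir-22, a miRNA abundant in striated muscle, the share was 14.9% in control and 10.4% in swim. The 10 most abundant entries of each library together held 82.0% of the control counts and 81.5% of the swim counts. Across the 191 entries, the log2 counts of the 2 libraries had a Pearson r of 0.95 and a Spearman rho of 0.97. These are correlations across genes, which are not independent replicates. Within the first part of the table (75 entries) Pearson's r was 0.98, and within the second part (116 entries) it was 0.78. Spearman's rho was 0.98 in the first part and 0.90 in the second.

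The comparison of swim with control asks which cardiac miRNAs differ in the exercised heart. Of the 173 entries tested, 6 were at least 2-fold higher in swim and 57 were at least 2-fold lower, which are 5 and 50 distinct miRNAs. The higher ones were mir-204, mir-208b, mir-148b, both copies of mir-19b, and mir-671. The lower ones included mir-345, both copies of mir-29b, mir-17, mir-9a and mir-210. Of these mir-671 and mir-210 lie outside the rule for named entries and were chosen after their values were seen. The calls were not spread evenly over the table. Of the 75 entries in its first, high-count part, 5 were higher and 1 was lower, mir-301a at 0.424 (chosen after its values were seen, and not a call under median-of-ratios factors, TMM factors or unscaled counts), and the median ratio was 1.06. Of the 98 entries in its second, low-count part, 1 was higher and 56 were lower, and the median ratio was 0.459. In the first part 43 entries lay above a ratio of 1 and 32 below, against 4 above and 94 below in the second part. The higher of the 2 counts separates the parts, so a high swim count alone can place an entry in the first part, as it did for 7 of the 75. Among these 7 are higher calls, mir-204 with 531 counts in control and both copies of mir-19b with 384. The contrast in higher calls between the parts is therefore partly set by how the parts are divided. Measured against the median of its own part instead, a setting chosen after seeing the data, 11 entries were higher and 11 lower. Of the 56 lower calls of the second part 10 were also called in this way, among them mir-345, let-7i and mir-201, while mir-29b, mir-17, mir-9a and mir-210 were not. The split of calls also moved with the scaling. Median-of-ratios factors raised the median log2 ratio of all entries by 0.59 and gave 18 higher and 26 lower calls, TMM factors raised it by 0.30 and gave 11 and 31, and counts with no rescaling raised it by 0.39 and gave 12 and 30. Entries with a ratio between 0.662 and 1 on the scale used here therefore lie above 1 under median-of-ratios factors. The bounds are 0.811 for TMM factors and 0.764 for unscaled counts.

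**Figure D1:**
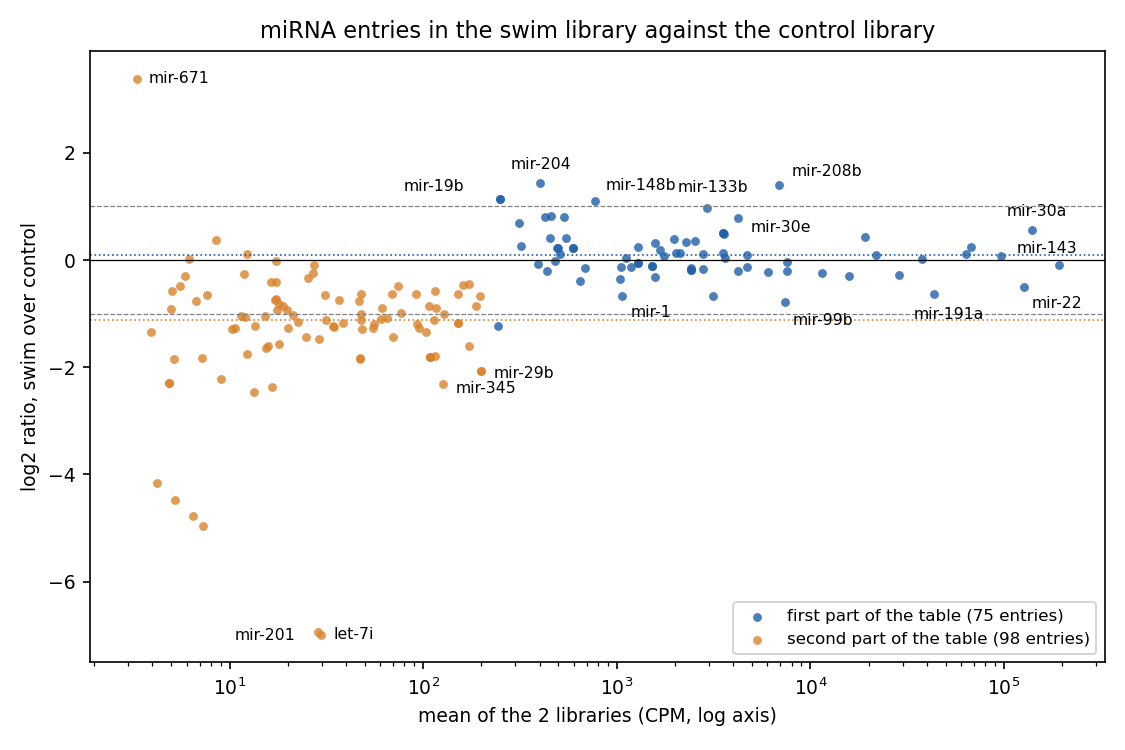
Each point is 1 of the 173 miRNA entries, with the mean of the 2 libraries in CPM on the horizontal log axis and the log2 ratio of swim over control on the vertical axis. Dashed lines mark 2-fold, and dotted lines mark the median of each part of the table, at ratios of 1.06 for the first part (blue) and 0.459 for the second part (orange).

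The muscle-enriched miRNAs differed from each other. The entry mir-208b, encoded in an intron of the slow myosin heavy chain gene Myh7, had 3801 CPM in control and 10049 CPM in swim, a ratio of 2.64 (95% interval 2.58 to 2.71). This was the second-highest ratio among the 75 first-part entries. Its relative mir-208a, encoded in Myh6, the fast cardiac myosin gene, had 721 CPM in control and 648 CPM in swim, a ratio of 0.899 (0.843 to 0.958) that lies above 1 under median-of-ratios factors, TMM factors and unscaled counts. The ratio of mir-208b to mir-208a, which no scaling can alter, was 5.27 in control and 15.5 in swim, a change of 2.94-fold (2.75 to 3.15). The entry mir-499, from another myosin gene, had a ratio of 1.19 (1.13 to 1.24). Its level was 1178 CPM in control and 1399 CPM in swim. For mir-133b the ratio was 1.95 (1.89 to 2.02), just under the size rule and past it under median-of-ratios factors, TMM factors and unscaled counts, and for mir-133a it was 1.18 (1.17 to 1.18). These hairpins give nearly identical mature miRNAs, so their reads may be split between the rows. The entry mir-1, which is made from the same primary transcript as mir-133a, had a ratio of 0.624 (0.593 to 0.658), below 1 under each scaling tried. The count of mir-133a was 47.1 times that of mir-1 in control and 88.8 times in swim. The mir-1 row held only 0.131% of the control and 0.0820% of the swim counts. The rule for reads that match several hairpins is not given, so whether this row holds all reads of mir-1 cannot be told. Of the 6 muscle entries measured, 1 was higher and 0 were lower, and their median log2 ratio of 0.24 stood at the 91.9th percentile of matched random lists.

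The miR-30 family, abundant in heart muscle, stood apart as a group. Of its 6 entries, 5 had ratios above 1, none passed the size rule on the scale used here, and the median log2 ratio of 0.51 lay above that of all 10000 matched random lists. The entry mir-30e had a ratio of 1.73 (1.68 to 1.77), mir-30a one of 1.47 (1.46 to 1.48) and mir-30c-1 one of 1.42 (1.38 to 1.47). The entry mir-30b had 1.09 (1.05 to 1.14), and the exception was mir-30d at 0.847 (0.834 to 0.860), which lies above 1 under median-of-ratios factors, TMM factors and unscaled counts. Under median-of-ratios factors 4 of the 6 were called higher (mir-30e, mir-30a and both mir-30c entries), and mir-30e was called higher under TMM factors and unscaled counts as well.

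The entries of the miR-29 family, known for targeting collagen transcripts, went apart. The ratio was 1.78 (1.64 to 1.93) for mir-29c, a higher call under median-of-ratios factors, TMM factors and unscaled counts, and 1.39 (1.36 to 1.43) for mir-29a, a higher call under median-of-ratios factors, while both copies of mir-29b were lower at 0.236 (0.204 to 0.273), with 795 counts in control and 246 in swim. Relative to its own part of the table mir-29b stood at a log2 ratio of -0.95, which is not a call. The mir-29c and mir-29b-2 hairpins are neighbours in the genome, and the ratio of their counts was 1.02 in control and 7.65 in swim. Both copies of mir-29b have equal counts, so the mir-29b-2 row does not measure the copy beside mir-29c alone. The entries mir-29c and mir-29a stand in the first part of the table and mir-29b in the second. With 810 counts in control and 1883 in swim, mir-29c reaches the first part's bound of 838 through its swim count only. Its control count was close to that of mir-29b. The parts therefore depend on the swim counts compared here, and the missing call relative to its own part does not discount the fall of mir-29b. The family's median log2 ratio of -0.80 stood at the 2.53rd percentile, at the edge of the central 95%, and at the 1.60th under median-of-ratios factors. With the copies of mir-29b summed it was 0.48, at the 84.9th percentile.

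The miR-99/100 and miR-125 families, which are clustered with let-7 genes, lay low. All 6 entries had ratios below 1 on the scale used here, mir-99b and mir-100 also under every other scaling, and none passed the size rule. The median log2 ratio of -0.24, which is positive under median-of-ratios factors, TMM factors and unscaled counts, stood at the 0.19th percentile of matched random lists under the scaling used here. The ratio was 0.578 (0.567 to 0.589) for mir-99b and 0.628 (0.609 to 0.647) for mir-100, against 0.896 for mir-99a, 0.803 for mir-125a and 0.924 for mir-125b-1. The miR-23/27/24 clusters, studied in cardiac hypertrophy, also had a low median, -0.18, which changes sign under the same 3 scalings, at the 1.66th percentile. Of those 6 entries none passed the size rule, and they ranged from 0.828 (0.820 to 0.836) for mir-27b to 1.08 for mir-27a. The percentile lay inside the central 95% once hairpin copies were summed.

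Among the other abundant entries, mir-191a had a ratio of 0.645 (0.639 to 0.650) and mir-22 one of 0.703 (0.699 to 0.706). The former stayed below 1 under every scaling, and the latter lies above 1 under median-of-ratios factors. The entries mir-10a at 1.05, mir-26a at 1.08 and mir-378a at 1.06 differed little between the libraries on the scale used here. Under median-of-ratios factors their log2 ratios were 0.67, 0.71 and 0.68. Among the 10 highest ratios were also mir-204 at 2.70 (2.45 to 2.98), mir-148b at 2.15 (2.01 to 2.30), mir-19b at 2.19 (1.95 to 2.47), mir-195 at 1.75 (1.62 to 1.89) and mir-490 at 1.74 (1.60 to 1.90), the last 2 of which are higher calls under median-of-ratios factors, TMM factors and unscaled counts. Of the 2 entries of the miR-26 family none passed the size rule, with mir-26b at 0.970.

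The markers of other cell types gave no call in the first part of the table. The endothelial entry mir-126a had a ratio of 1.01 (1.00 to 1.02). Of the vascular smooth muscle pair, mir-143 had 0.936 (0.933 to 0.940), which lies above 1 under median-of-ratios factors, TMM factors and unscaled counts, and its cluster partner mir-145 had 1.32 (1.27 to 1.37). The erythroid entry mir-144, with 72 counts in control and 80 in swim, had 0.849 (0.610 to 1.18). Of the 3 erythroid miRNAs in the list it was the only 1 with a tested entry, mir-451 and mir-486 having none. None of the 4 leukocyte entries passed the size rule, with mir-146a at 1.07, mir-150 at 0.908, mir-142 at 0.785 and mir-342 at 0.552, and their median stood at the 23.3rd percentile. Of the 3 fibroblast-associated entries 1 was lower. The ratio was 0.866 (0.850 to 0.883) for mir-21, 1.25 (1.20 to 1.30) for mir-199a and 0.370 (0.296 to 0.461) for mir-214, whose call is lost under median-of-ratios factors and relative to its own part (log2 ratio -0.31), and the list's median stood at the 38.1st percentile. Of the 11 entries typical of liver, brain, endocrine or epithelial tissue, 6 were lower and none higher, with mir-9a-1 at 0.287 (0.237 to 0.345), not a call relative to its own part (log2 ratio -0.68), and mir-192 at 1.03, and their median stood at the 9.93rd percentile. Of the 11, which stand for 8 distinct miRNAs, 4 were lower under each of median-of-ratios factors, TMM factors and unscaled counts. All copies of mir-9a, which have equal counts, are among the 6 and among these 4. Relative to their own part 1 of the 11 entries was lower, an entry listed at 1 in swim, and 1 higher.

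Of the 12 entries of the miR-17-92 and paralogous clusters, 2 were higher (the mir-19b copies) and 6 were lower, and the list's median log2 ratio of -1.03 stood at the 17.9th percentile. Of the 12, 4 were lower under each of median-of-ratios factors, TMM factors and unscaled counts. Relative to its own part 1 was lower, an entry listed at 1 in swim. The 12 stand for 9 distinct miRNAs, and both mir-17 copies, with nearly equal counts, are among the 4. Within this list the count of mir-19b-1 was 2.10 times that of mir-17-1 in control and 16.7 times in swim, a change of 7.95-fold (5.86 to 10.8). Against mir-19a, which lies outside the rule for named entries, it was 8.17 times in control and 61.2 times in swim. The mir-19a row held 47 counts in control and 18 in swim. Why mir-19b parted from these entries was not tested. The entry mir-92a-1 had a ratio of 1.10 and mir-25 one of 1.15. Of the 6 Dlk1-Dio3 entries, an imprinted cluster that is active in fetal tissue, 2 were lower, and the median of -0.99 stood at the 48.0th percentile. In that cluster mir-127 had a ratio of 0.951, which lies above 1 under median-of-ratios factors, TMM factors and unscaled counts, and mir-410 one of 0.447. Both miR-34 entries were lower on the scale used here, mir-34a at 0.459 and mir-34c at 0.415. Of the pair mir-221 and mir-222, the latter was lower at 0.424 (0.309 to 0.577) and the former had 0.625. The entry mir-132 had a ratio of 1.08 (0.655 to 1.80) on 29 counts in control and 41 in swim, and was called higher relative to its own part, at 2.36 (1.43 to 3.93). Its cluster partner mir-212, too low in count to be tested and outside the rule for named entries, was listed at 1 in control and 7 in swim. Of the 5 entries of the miR-15/16 family 1 was lower, mir-497 at 0.414 (0.344 to 0.498), and the median stood at the 76.3rd percentile. The lower calls of mir-34a, mir-34c, mir-222, mir-410, mir-409a and mir-497 are each lost under median-of-ratios factors, TMM factors and unscaled counts, and relative to their own part. None of the 5 miR-181 entries passed the size rule, and they ranged from 0.811 for mir-181a-1 to 1.27 for mir-181c, with the median at the 73.9th percentile. Of the 3 let-7 entries with a ratio 1 was lower, let-7i, which was listed at 145 counts in control and 1 in swim. The others, let-7c-1 and let-7a-2, had ratios of 0.910 and 0.858, and the median stood at the 39.6th percentile. The let-7 list names 9 miRNAs, so these 3 entries cover only a part of the family.

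The list of miRNAs studied in cardiomyocyte apoptosis shares many members with the lists above. Of its 22 entries 2 were higher and 3 were lower, against 6 and 1 under median-of-ratios factors, 4 and 2 under TMM factors or unscaled counts, and 2 and 0 relative to the own part. Its median log2 ratio of 0.11 stood at the 99.8th percentile, while its mean was -0.03, of the opposite sign. The 2 higher entries were the copies of mir-19b, and the lower ones were mir-34a, mir-210 and mir-214. Of the 9 entries tied to energy metabolism 3 were lower and none higher, among them mir-210, a miRNA induced by hypoxia, at 0.288 (0.239 to 0.345), not a call relative to its own part (log2 ratio -0.67). Of the 9, 2 were lower under each of the other 3 scalings and 1 relative to its own part. The median of that list stood at the 88.9th percentile.

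**Figure D2:**
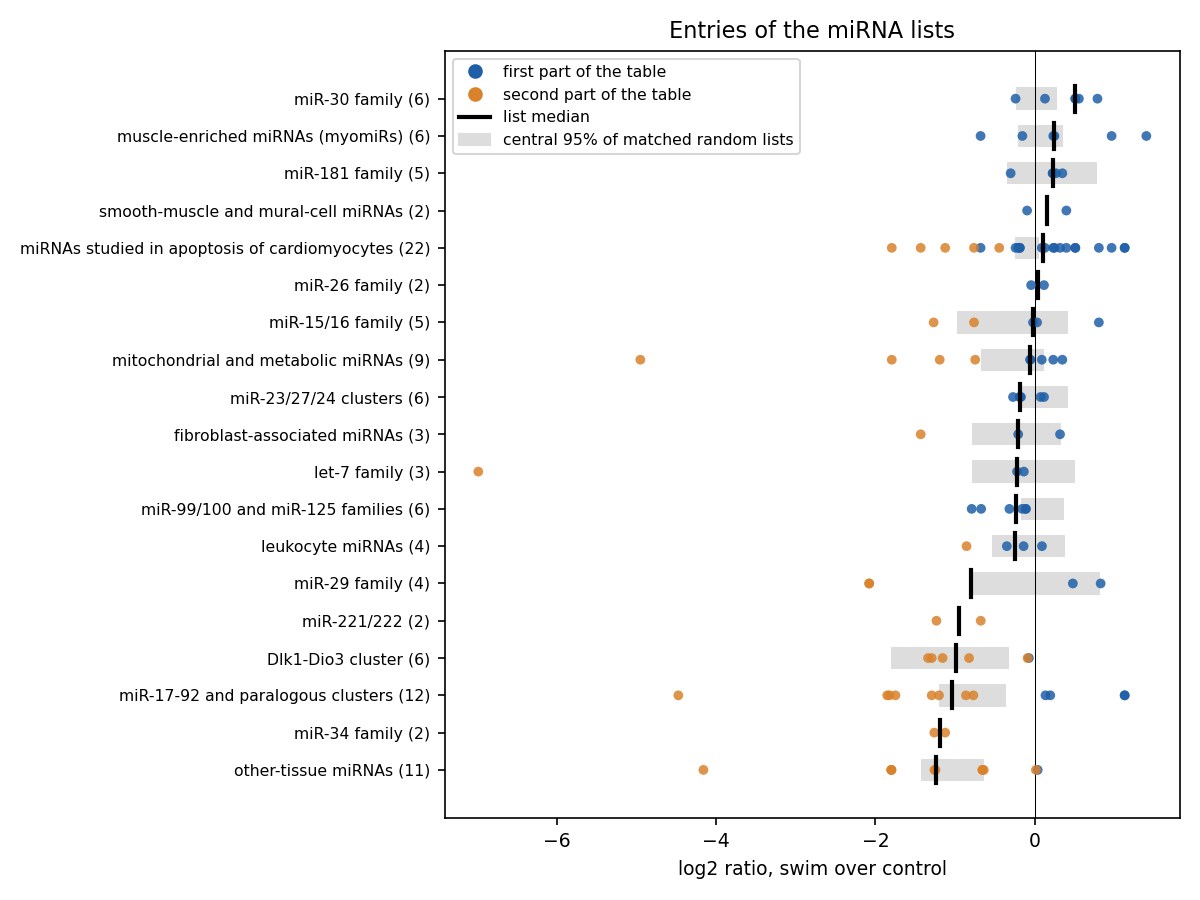
Each point is an entry of a list, placed by its log2 ratio of swim over control on the horizontal axis, with the number of entries in parentheses after the list's name. Black bars are list medians and grey bars span the central 95% of 10000 matched random lists, which the miR-30 and apoptosis lists exceed and the miR-99/100 and miR-125 and the miR-23/27/24 lists fall below. Lists with 2 entries have no grey bar.

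The lowest ratios belonged to let-7i, with 0.00527 (0.000133 to 0.0298), and mir-201, with 0.00546 (0.000137 to 0.0309). Each rests on a listed value of 1 in swim. In all, 6 of the 57 lower calls stood at 1 in swim, and of the 6 higher calls mir-671, at 1 in control and 20 in swim, stood at 1. Next among entries with a summed count of at least 100 came mir-345 at 0.200 (0.164 to 0.242), mir-29b, and mir-17-1 at 0.276 (0.205 to 0.367). Among entries with a ratio, the counts of the swim library left a gap that those of the control library did not. Between 490 and 1101 no such swim entry was found, and 17 control entries fell there. The let-7e rows, which have no ratio, include a swim count of 821 inside this range.

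**Figure D3:**
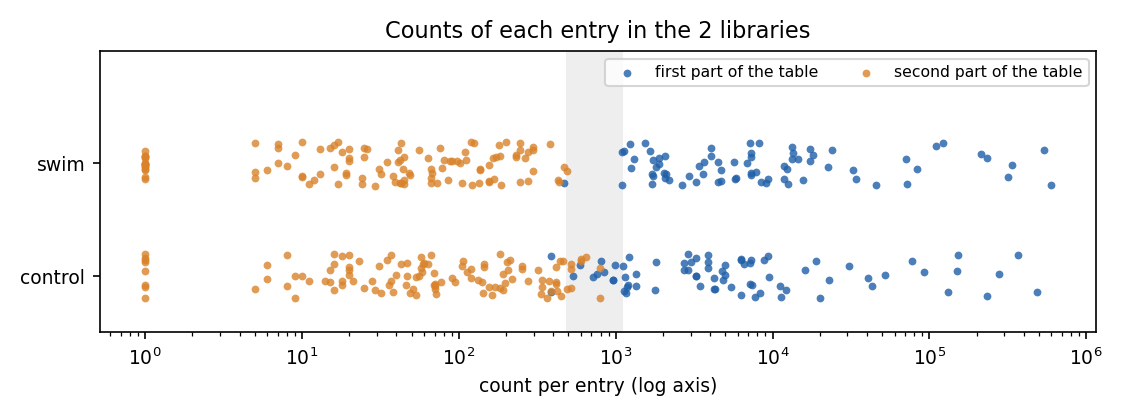
Counts of each of the 191 entries are plotted on a log axis for the control and the swim library, with points shifted vertically at random for legibility. The grey band spans 490 to 1101 counts, which holds none of these entries in swim and 17 in control. The let-7e rows, which include a swim count of 821, are not shown.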

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

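The test reported here was chosen after the counts were seen. The row named Others, which belongs to no miRNA and enters no comparison, held 12.5% of the swim counts (95% exact binomial interval 12.47 to 12.54%) against 5.41% of the control counts (5.39 to 5.44%), a 2.31-fold larger share. It stood out as a signal outside the measured miRNAs that was above the control level. One candidate explanation is that reads of low-count miRNAs were moved into this row in the swim library. The reads missing from the second part of the table, measured against the first part's median ratio, came to 14039, which is 5.09% of the 276020 reads that Others gained over the control rate, so such a move is too small to be the whole source of the gain. What the row holds is not given in the sources used here, and no biological explanation was tested.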

How the results depend on the processing

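No paired analysis was possible because each condition has 1 library and the labels give no replicate numbers, and no library could be left out. Settings that measure entries against their own part of the table, average equal copies, include Others, drop entries at 1 or keep asterisk rows were chosen after seeing the data. Counts at least 2-fold higher and lower, 6 and 57 as reported, were 18 and 26 with median-of-ratios factors, 11 and 31 with TMM factors, 12 and 30 with no rescaling, and 11 and 11 relative to the median of the own part. The lower count was 36 with a summed count of at least 100, where fewer entries were tested. With the size rule at 1.5-fold 12 entries were higher and 82 lower, and at 3-fold 1 was higher and 26 were lower. Of the 6 higher calls, 6 were also called under each scaling of the miRNA counts, and 5 with Others in the total. Of the 57 lower calls, 26 were also called with median-of-ratios factors, 31 with TMM factors and 11 relative to the own part. The median log2 ratio of the miR-23/27/24 clusters turned to 0.42, 0.12 and 0.21, and that of the miR-99/100 and miR-125 families to 0.36, 0.065 and 0.15, with median-of-ratios factors, TMM factors and no rescaling, since one factor shifts every entry. That of the apoptosis list turned to -0.00305 with Others in the total. Relative to its own part, mir-34a turned to 0.000623. Between 3 and 5 lists lay outside the central 95% of random lists. The miR-30, miR-99/100 and miR-125, and apoptosis lists did so under each setting. The miR-29 list, inside that range as reported, lay outside it with median-of-ratios factors (1.60th percentile), without the most abundant entry in the total (2.40th), with Others in the total (2.35th) and with asterisk rows kept (2.43rd). Its median turned to 0.48 with hairpin copies summed or averaged. The Dlk1-Dio3 list lay above that range with a summed count of at least 100, and the miR-23/27/24 list lay inside it with hairpin copies summed or averaged. The 10 most abundant entries held 77.5% (control) and 77.2% (swim) when mir-143 was left out of count and total. The other values are single entries and lists: 816 of the named entries' values and 195 of the lists' stayed within their counting interval or within 0.1, and 362 and 105 did not, with no change of direction in a call. Changes of sign occurred among the latter too. With median-of-ratios factors the medians of the leukocyte, fibroblast-associated, let-7 and miR-15/16 lists turned from negative to 0.35, 0.39, 0.37 and 0.57. Single entries such as mir-21 and mir-27b turned to 0.39 and 0.32. Depth limits the second part of the table, which held 0.746% of the control and 0.357% of the swim counts.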

Other observations

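Some abundant miRNAs outside the lists had ratios somewhat above 1 and under the size rule. The mir-10 pair, which lies in the Hox gene clusters, had ratios of 1.05 for mir-10a and 1.35 (95% interval 1.33 to 1.36) for mir-10b. The mir-101 pair had 1.25 for mir-101a and 1.17 for mir-101b. Apart from mir-10a, these entries, like mir-130a at 1.33 (1.24 to 1.43) and mir-140 at 1.32 (1.22 to 1.43), were chosen after their values were seen.

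The tests in the next 2 paragraphs were chosen after the result was seen, as was the test on neighbours split over the parts in the last paragraph. The test on neighbours within a part was chosen before. Entries of the second part of the table lay lower in swim than those of the first, by -1.21 in median log2 ratio (95% bootstrap interval -1.36 to -0.9998). Because the higher of the 2 counts separates the parts, entries with a high swim count stand in the first part, which widens this difference. The tests were therefore made with the boundary set on the control count alone, at 838. Entries below it lay lower than those above it by -1.09 (-1.27 to -0.89). A library size, or a few abundant miRNAs setting the scale, acts on each entry alike and cannot give this difference. Counting noise of low counts is also argued against, since 81 of the 105 entries below the boundary had an interval wholly below the median ratio of those above it and 8 had one wholly above it. The 2 parts having been made or scaled separately stays open and fits the step at this boundary. A model with a slope on the log2 control count, over 166 entries above 1 in both libraries, put this step at -0.96 (-1.36 to -0.52). With the parts as they stand and a slope on the log2 mean instead, the step was -1.48, so boundary and slope both differ. Shuffling ratios among 40 neighbouring entries gave a gap in the swim counts as wide as the observed one with a permutation p of 0.0006. That gap was seen beforehand, spans the boundary and leaves out a let-7e swim count of 821, so it is no separate support. A response of low-abundance miRNAs to swimming was not tested. It cannot be told apart from separate making or scaling of the parts with 1 library per condition.

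The entry mir-208b was higher in swim while mir-208a was not. Reads of mir-208a counted at mir-208b are argued against as the source of the higher mir-208b, since the summed counts of the 2 rows, which such a move leaves alone, had a ratio of 2.37 (2.32 to 2.42). Such a move in the swim library only stays open as the source of the lower ratio of mir-208a: with 3405 of the 32356 swim reads of mir-208b moved back, both would have the same ratio. Scaling cannot produce the 2.94-fold change (2.75 to 3.15) in the ratio of mir-208b to mir-208a. Whether swimming or a difference between single animals or libraries gave it cannot be told apart, because no condition has a second library.

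A hypothesis written beforehand was that hairpins made from one primary transcript have like ratios. These were taken as entries within 10 kb of each other whose hairpin had 1 listed copy. Some of them, such as let-7a-2 and let-7c-1, carry a copy number, so their rows may hold reads of unlisted copies. Over 26 pairs of such neighbours within a part of the table, the mean absolute difference in log2 ratio was 1.07, against 0.92 for permuted pairs (one-sided permutation p = 0.737). Without pairs that hold an entry at 1, a restriction added later, it was 0.44 over 22 pairs against 0.58 (permutation p = 0.0658). The threshold was missed both times, which does not exclude the hypothesis, and the bound written beforehand was wrong in treating a missed threshold as an exclusion. Choosing the 15 pairs split over the 2 parts by their parts already sets the direction of their difference, so it was compared with ratios permuted within each part. The median difference, second part minus first, was -0.79, against a permuted median of -1.14 (central 95% -1.84 to -0.61; one-sided permutation p = 0.0957). This misses the threshold, and 6 of the 15 pairs come from one cluster, mir-322, mir-450a and mir-351 with mir-542 and mir-503. With these few pairs it stays open whether split neighbours differ less than other entries of the 2 parts.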
